A study of Mus musculus with 28 samples.

How the data were processed

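Bulk RNA sequencing of 28 liver samples was re-analysed, 16 from mice on the alcohol diet and 12 from mice on chow, 14 of them tumors and 14 non-tumor liver. The labels give a DEN dose of 25 mg/kg at 2 weeks of age and 18 weeks of feeding, and name the diet both as a high-fat diet with alcohol and as liquid ethanol feeding; it is called the alcohol diet here. They name polyA RNA as the molecule and a stranded total RNA kit for the library, so the RNA fraction sequenced remains open. Groups were formed by genotype, diet and tissue from the sample labels, with n = 4 for each alcohol group and n = 3 for each chow group. The labels give no sex.

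The deposited values are gene-level CPM (counts per M) for 22187 genes, made by the authors per their processing notes with STAR 2.5.1a and RSEM 1.3.0 on GRCm38. Each column sums to 1000000, and no further step is given in the sources used here. Symbols and positions came from the GENCODE annotation for 21653 gene IDs; the 534 others held at most 0.166% of the CPM of a library. The table held 0 genes of chromosome Y and 0 of the mitochondrial chromosome, and Xist was not analysed here. No column belonged to another sample. Reads per library were estimated from the smallest step between low values and ranged from 9.57 to 17.82 M (M, 1000000 reads). Of values up to 20 reads 85.9% were whole reads to within 0.1 read (84.8% to 87.0% by library), too few to treat the values as counts, so no count model was used. Mean reads were lowest in dHEP chow non-tumor liver (11.6 ± 1.65 M) and highest in FF chow tumors (17.16 ± 0.63 M); FF chow non-tumor liver spread from 9.57 to 16.88 M. Genes at 1 CPM or more numbered 11920 to 13134 in tumors and 11864 to 12596 in non-tumor liver. The highest Pearson r between 2 libraries was 0.9913, between libraries of different groups, so none was taken as a duplicate.

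Tests used limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend, on log2(CPM + 1), for genes at 1 CPM or more in at least 3 of the fitted libraries. Genotype and diet were compared within each tissue in a fit of its 14 libraries, and tumor with non-tumor liver in a fit of all 28 (13503 genes). Differences of the genotype effect between diets and, on alcohol, between tissues were tested as interactions. A gene was called at an adjusted p < 0.05 by the Benjamini-Hochberg method (BH) over all tested genes; log2 fold changes are given ± standard error and CPM as mean ± standard deviation. Il17ra, Lcn2, Srebf1, Srebf2, Dhcr7 and Casp2 were fixed before the values were seen and were also adjusted over those 6 genes and tested by exact permutation of the libraries. With n = 4 against 4 the exact p cannot be below 0.029 and with 3 against 3 not below 0.1.

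Gene lists (36, of which 23 were pathways and 13 cell types; 512 genes, 11 not found in the table) were written from general knowledge before any test, and 34 had enough genes. They were tested by the competitive camera test in limma with a preset inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted by BH over the 34 lists. Members were counted as passing over all genes and, separately, adjusted over the list alone.

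Genes to name were chosen by rule among called genes with a mean of 5 CPM or more in the higher group and every library of 1 group above every library of the other: the 10 largest rises and 10 largest falls, or 5 and 5 for the diet and tissue comparisons in dHEP mice, leaving out unnamed transcripts and antigen receptor segments. Not all of these were printed, some being not reported here, and for each list up to 4 members of smallest p were named. Afp and Gpc3 in the genotype comparison, and the list members that ran against their list (Plin5 in FF non-tumor liver and 7 genes in the tumor lists), were chosen after their values were seen.

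The number in each sample name was taken as the animal number. Tumor and non-tumor liver share animals in FF alcohol, dHEP alcohol and dHEP chow, and in FF chow the numbers differ. Deviations of samples with the same number from their group means correlated at 0.16 to 0.36 in FF alcohol (all 4 pairs above 0.1), -0.11 to 0.25 in dHEP alcohol (2 of 4) and 0.07 to 0.19 in dHEP chow (2 of 3). The animal as a block, fitted in the compared groups only, was an alternative fixed beforehand. The other alternatives fixed beforehand were a pseudocount of 0.5, no filter, a filter at a mean of 5 CPM, median-of-ratios scaling between libraries, sample quality weights, a fit of the 2 compared groups only, and leaving out each library in turn. Leaving out the FF alcohol non-tumor libraries FF-523 and FF-581, or the chow non-tumor libraries dHEP-155 and FF-158, list tests without tumor dHEP-549, and both models that pool the diets, were added after the results had been seen. List tests in all these alternative fits used the preset correlation only.

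Each fit was tested on simulated data with means, spreads and depths taken from the real libraries and 200 genes changed in 1 group, 100 of them 2-fold and 100 of them 4-fold. Each gene had 1 spread, pooled over both tissues, and its noise was drawn independently of other genes. Real genes move together and tumors vary more between animals, so the figures need not hold for the real fits. In genes of 5 to 500 CPM, 48 to 70 of 100 genes changed 2-fold were called in 11 of the 12 comparisons and 16 in the diet comparison of dHEP non-tumor liver. At 4-fold 90 to 98 were called, with 5 to 13 unchanged genes called besides. The pool was narrowed to that range after a first simulation on all genes above 5 CPM. There, for dHEP alcohol tissue, 3850 unchanged genes were called, as the changed genes held 9.26% of the CPM and shifted the rest by a median of -0.41, while in the diet comparison of dHEP non-tumor liver 2 of 100 were called at 2-fold and 76 at 4-fold. The low figure at 2-fold in that comparison, 16 and 2 of 100, is not accounted for by this shift. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.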

Results

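Gene-level RNA values were compared between liver tumors and non-tumor liver of C57BL/6 mice given diethylnitrosamine (DEN), a liver carcinogen, at 2 weeks of age and then kept on an alcohol diet or on chow for 18 weeks. The gene for the interleukin-17 receptor A chain, Il17ra, was floxed in all mice. In dHEP mice a Cre driven by the albumin promoter was also present, which removes the receptor from hepatocytes, and FF mice carried the floxed gene alone. The 28 libraries formed 8 groups, with n = 4 per group on alcohol and n = 3 per group on chow. The deposited values were CPM (counts scaled to a total of 1000000) per gene. Each library held 9.57 to 17.82 M reads as estimated from the step between its lowest values. At that depth 1 CPM stood for 9.57 to 17.82 reads, so genes below about 1 CPM were left untested. Animal numbers started at FF-503 on alcohol and ended at FF-169 on chow, so diet cannot be told apart from cohort. The labels name the alcohol diet also as a high-fat diet. Ethanol can therefore not be told apart from other differences between that diet and chow.

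Il17ra, the targeted gene, was lower in non-tumor liver of all dHEP mice than in that of all FF mice. In dHEP non-tumor liver on alcohol it read 13, 11.2, 9.23 and 11.5 CPM (dHEP-518, dHEP-520, dHEP-549 and dHEP-550), and on chow 8.34, 10.4 and 9.98 CPM (dHEP-155, dHEP-164 and dHEP-165). In FF non-tumor liver it read 17.6, 29.4, 18.5 and 31.0 CPM on alcohol (FF-503, FF-523, FF-581 and FF-595), and 23.1, 20.2 and 14.7 CPM on chow (FF-157, FF-158 and FF-159). Tumors of dHEP mice read 15.5, 28.3, 8.38 and 10.7 CPM on alcohol and 29.4, 13 and 15.4 CPM on chow, in the same order of mice. Tumors of FF mice read 33.9, 31.1, 20.9 and 27.9 CPM on alcohol, in the same order, and 29.9, 20.8 and 30.1 CPM on chow (FF-167, FF-168 and FF-169). The tumors dHEP-520 and dHEP-155, at 28.3 and 29.4 CPM, thus lay inside the FF tumor range of 20.8 to 33.9 CPM.

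Il17ra in dHEP non-tumor liver stood at 46.6% of the FF mean on alcohol (11.2 ± 1.55 against 24.1 ± 7.03 CPM, n = 4 each, log2 fold change -1.0 ± 0.19, exact p = 0.029, the smallest possible with these group sizes). On chow it stood at 49.6% (9.59 ± 1.1 against 19.3 ± 4.27 CPM, n = 3 each, -0.92 ± 0.22, exact p = 0.1, again the smallest possible). In tumors it stood at 55.2% on alcohol (15.7 ± 8.87 against 28.4 ± 5.6 CPM, exact p = 0.086) and at 71.5% on chow (19.3 ± 8.83 against 26.9 ± 5.36 CPM, exact p = 0.2). Adjusted over the 6 genes fixed beforehand by limma with the Benjamini-Hochberg method (BH), the loss passed in non-tumor liver on alcohol (adjusted p = 0.00081) and on chow (adjusted p = 0.0059). It did not pass in tumors on alcohol (adjusted p = 0.084) or on chow (adjusted p = 0.38). Over all genes the adjusted p for Il17ra was 0.29 in non-tumor liver on alcohol and 0.72 on chow. Adjusted by BH over the 24 exact tests of these genes, the smallest p was 0.34.

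**Figure D1:**
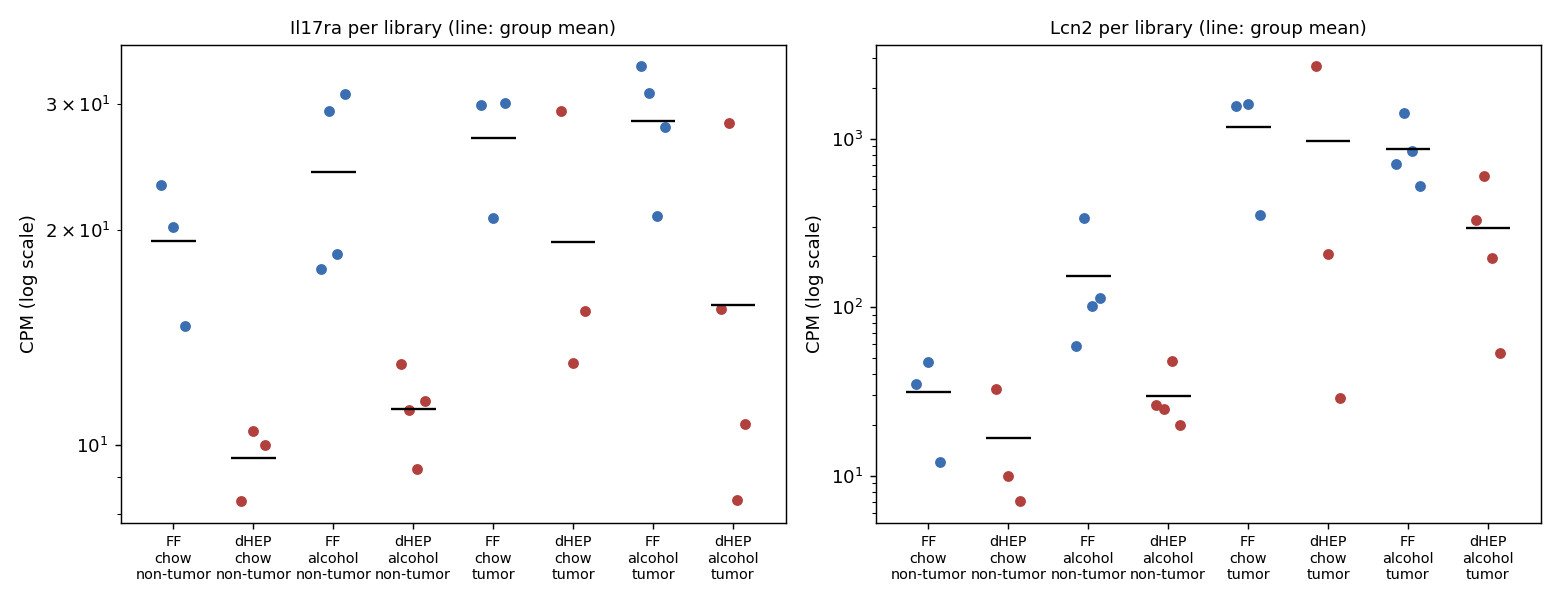
CPM of Il17ra and of Lcn2 on a log axis in the 8 groups, with a dot per library (blue FF, red dHEP) and a line at the group mean. Il17ra in non-tumor liver ran from 8.34 to 13 CPM in dHEP and from 14.7 to 31 CPM in FF, and mean Lcn2 on alcohol in non-tumor liver was 29.7 CPM in dHEP against 153 CPM in FF.

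In alcohol-fed non-tumor liver, Lcn2, which encodes the secreted iron-sequestering protein lipocalin-2 and is induced by interleukin-17, averaged 29.7 ± 12.3 CPM in dHEP against 153 ± 127 CPM in FF (n = 4 each). This was 19.4% of the FF mean (log2 fold change -2.09 ± 0.56). It passed when adjusted over the 6 preset genes (adjusted p = 0.0066, exact p = 0.029) and not over all genes (adjusted p = 0.37). FF-523 alone held 339.6 CPM of Lcn2, and without it dHEP stood at 32.7% of the FF mean (-1.60 ± 0.51, adjusted p over the preset genes = 0.024). Without FF-523 and FF-581 it stood at 34.7% (-1.50 ± 0.60) and Lcn2 no longer passed (adjusted p = 0.085). Of the other preset genes, Srebf2, the activator of cholesterol synthesis genes, stood at 18 ± 1.25 against 23.8 ± 3.15 CPM (adjusted p over the preset genes = 0.092). Srebf1, the activator of fatty acid synthesis genes, stood at 316 ± 52.6 against 380 ± 174 CPM. Dhcr7, an enzyme of late cholesterol synthesis, stood at 14.2 ± 3.39 against 28.4 ± 16.1 CPM, and the caspase gene Casp2 at 6.29 ± 1.2 against 6.61 ± 2.4 CPM. None of Srebf1, Dhcr7 and Casp2 passed after adjustment.

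No gene passed BH over all 12651 tested genes in alcohol-fed non-tumor liver. At unadjusted p < 0.05 there were 1077 genes where chance alone gives 633, and the smallest adjusted p was 0.095, for Fat1, an atypical cadherin. The gene list of interleukin-17 targets, 15 genes, lay lower in dHEP (median log2 fold change -0.62, list test adjusted p = 0.00083, and adjusted p = 0.48 with an estimated correlation). Besides Lcn2, adjusted over the list alone, the chemokine gene Ccl2 was lower (0.803 ± 0.59 against 2.85 ± 1.72 CPM, adjusted p = 0.048). Nfkbia, an inhibitor of NF-kB, was higher (49.7 ± 4.89 against 37.3 ± 7.13 CPM, adjusted p = 0.048). Over all genes 0 of the 15 passed. The 17 interferon response genes lay lower (median -0.59, adjusted p = 1.3e-05, and adjusted p = 0.5 with an estimated correlation). Isg15, an antiviral ubiquitin-like protein, stood at 2.39 ± 0.336 against 5.81 ± 1.69 CPM and was the 1 member passing over the list alone, with 0 over all genes. The 13 p53 targets lay lower (median -0.34, adjusted p = 0.00042, and adjusted p = 0.42 with an estimated correlation). The p53-induced receptor Eda2r stood at 3.34 ± 1.24 against 7.77 ± 2.22 CPM (adjusted p over the list alone = 0.0087). It was the 1 member passing over the list, and 0 passed over all genes. The 13 genes of MAPK and DEN-tumor signalling lay lower (median -0.49, adjusted p = 3.6e-05, and adjusted p = 0.42 with an estimated correlation). Over the list alone 2 members passed, and 0 over all genes. They were Phlda1 at 8.01 ± 1.66 against 21 ± 6.43 CPM and Dusp5 at 0.808 ± 0.204 against 3.96 ± 3.21 CPM. The 10 genes of monocytes and recruited macrophages (median -0.75, adjusted p = 0.00049, and adjusted p = 0.5 with an estimated correlation) and the 7 MHC class II genes (median -0.51, adjusted p = 0.04, and adjusted p = 0.53 with an estimated correlation) lay lower too, with 0 passing over all genes or over the list alone. Of the 34 lists 14 were called lower and 7 higher. Without single libraries Eda2r kept its call over the list in all 8 fits. Ccl2, Nfkbia, Isg15, Phlda1 and Dusp5 lost theirs in 4 to 7, spread over all the libraries but FF-595 (adjusted p up to 0.19), and without FF-581 mean Dusp5 in FF was 2.448 CPM.

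The 16 cytochrome P450 and regulator genes lay higher in dHEP non-tumor liver on alcohol (median 0.34, adjusted p = 5.3e-08, and adjusted p = 0.055 with an estimated correlation). Adjusted over the list alone 3 were higher and over all genes 0. Nr1i3, the drug-sensing receptor CAR, stood at 433.1 ± 164.3 against 222 ± 45.5 CPM (log2 fold change 0.91 ± 0.25). The others were Cyp2c54 at 234 ± 36.1 against 147 ± 60.6 CPM, and Nr1i2, the drug-sensing receptor PXR, at 87.1 ± 2.17 against 72.7 ± 9.48 CPM. The 18 bile acid genes lay higher (median 0.21, adjusted p = 2.9e-05, and adjusted p = 0.055 with an estimated correlation). Over the list alone 2 passed and over all genes 0. The bile acid importer Slc10a1 was higher (438 ± 23.6 against 342 ± 23.8 CPM), as was Cyp7a1, the first enzyme of bile acid synthesis (490 ± 143 against 195 ± 117 CPM, 1.48 ± 0.45). Each of these 5 members lost its call over the list in 3 to 7 of the 8 fits without 1 library, spread over all 8 libraries (adjusted p up to 0.15). The 16 genes of the unfolded protein response lay lower (median -0.42, adjusted p = 0.00049, and adjusted p = 0.48 with an estimated correlation), with 0 passing over all genes or over the list alone. The 14 tumor markers lay lower (median -1.08, adjusted p = 3.4e-06, and adjusted p = 0.48 with an estimated correlation), with 0 passing over all genes and 1, Lcn2, over the list alone. Afp, the fetal liver protein alpha-fetoprotein, stood at 2.66 ± 0.447 CPM in dHEP and 95.6 ± 107 CPM in FF, and the oncofetal proteoglycan gene Gpc3 at 1.78 ± 0.756 against 12.1 ± 11.6 CPM.

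The FF spread of Afp and Gpc3 came from 2 mice, whose non-tumor libraries FF-523 and FF-581 held Afp at 213 and 159.2 CPM and Gpc3 at 25.8 and 17.6 CPM. In FF-503 and FF-595 Afp stood at 8.82 and 1.47 CPM and Gpc3 at 3.80 and 1.09 CPM. The lists were retested without those 2 libraries, with n = 2 left in FF, at the preset correlation only. With all libraries no list was called at an estimated correlation. Without the 2 libraries 9 of the 21 called lists remained called: interleukin-17 targets (adjusted p = 3.6e-05), interferon (0.00028), p53 (0.0046), MAPK (0.0013), cytochrome P450 (6.8e-05), bile acid (0.039), unfolded protein response (1.3e-08), acute phase (1.3e-08) and fatty acid oxidation (2e-06). With all libraries the last 2 had medians of -0.30 and 0.10 (adjusted p = 0.0034 and 0.00065, and adjusted p = 0.53 and 0.5 with an estimated correlation), with 0 passing over all genes or over the list alone. The tumor markers no longer passed (adjusted p = 0.055), nor did the monocyte genes (0.16), MHC class II genes (0.45) or cholesterol synthesis (0.99, with all libraries median -0.38, adjusted p = 0.00049 and 0.53 with an estimated correlation).

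In alcohol-fed tumors the unfolded protein response genes, which raise folding capacity of the endoplasmic reticulum, lay lower in dHEP (16 genes, median -0.63, adjusted p = 1.3e-07, and adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone 5 genes were lower, and 0 over all genes. Among them were the folding helpers Dnajb9 (54.1 ± 16.6 against 93 ± 25.6 CPM, n = 4 each) and Hyou1 (261 ± 41.8 against 429 ± 111 CPM). The main chaperone Hspa5 stood at 1010 ± 157.8 against 1760 ± 498 CPM (log2 fold change -0.76 ± 0.25) and the stress-induced pseudokinase Trib3 at 18.5 ± 15.6 against 57.1 ± 26.3 CPM. The 21 fibrosis genes lay lower (median -0.40, adjusted p = 0.00052, and adjusted p = 0.62 with an estimated correlation). None passed over all genes and 2 did over the list alone. Acta2, a contractile marker of activated stellate cells, was lower (9 ± 2.81 against 31.2 ± 10.5 CPM, -1.68 ± 0.30, adjusted p over the list = 0.0017). So was the actin-binding gene Tagln (9.21 ± 2.76 against 21.3 ± 3.48 CPM, -1.15 ± 0.25, adjusted p over the list = 0.0051). The 18 bile acid genes lay higher (median 0.65, adjusted p = 3.5e-05, and adjusted p = 0.35 with an estimated correlation). The 1 member passing over the list alone, with 0 over all genes, was the bile acid-conjugating enzyme gene Slc27a5 (410 ± 141 against 201 ± 19.3 CPM, 0.96 ± 0.25). The 16 cytochrome P450 and regulator genes also lay higher (median 0.65, adjusted p = 0.00033, and adjusted p = 0.44 with an estimated correlation). Their 1 member over the list alone, with 0 over all genes, was Por, the electron donor of cytochrome P450 enzymes (214 ± 49.6 against 107 ± 22.8 CPM, 0.99 ± 0.24). Without single libraries Acta2 and Tagln kept their calls over the list in all 8 fits. Dnajb9, Hyou1, Hspa5, Trib3, Slc27a5 and Por lost theirs in 3 to 6, when dHEP-549, dHEP-550 or an FF tumor was left out (adjusted p up to 0.16). Without dHEP-518 mean Trib3 in dHEP was 11.68 CPM. The 19 tumor markers lay lower (median -1.03, adjusted p = 0.00055, and adjusted p = 0.53 with an estimated correlation) and the 13 hepatocyte genes higher (median 0.14, adjusted p = 0.0073, and adjusted p = 0.44 with an estimated correlation), with 0 passing in either over all genes or over the list alone. Tumor dHEP-549 held Afp at 5.47 and Gpc3 at 0.473 CPM and lay between the tissues on the first principal component. Without it 12 of the 17 called lists remained, among them all 4 named before these, while the tumor markers (median -0.47, adjusted p = 0.056) and hepatocyte genes (adjusted p = 0.072) lost their call. Lcn2 stood at 294 ± 232 against 873 ± 386 CPM (-1.93 ± 1.10, adjusted p over the preset genes = 0.3, exact p = 0.057), with a dHEP mean of 193 CPM without dHEP-520 (-2.42 ± 1.17), and -1.27 ± 1.12 without dHEP-550. None of the 13205 tested genes passed over all genes, with 833 at unadjusted p < 0.05 where chance alone gives 660. The smallest adjusted p was 0.57, for Acta2.

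On chow, Il17ra was again the gene of its 6-member pathway list that was lower in dHEP non-tumor liver (0 of 6 over all genes, 1 over the list alone). The list median was -0.10 (adjusted p = 0.032, and adjusted p = 0.67 with an estimated correlation), and its call ended without dHEP-155 and FF-158 (adjusted p = 0.12), when 9 of the 15 called lists remained. The fatty acid oxidation genes lay lower (22 genes, median -0.30, adjusted p = 1.4e-12, and adjusted p = 0.39 with an estimated correlation). Over the list alone 6 passed, and 0 over all genes. Among them (n = 3 each) were the mitochondrial dehydrogenase gene Acadl (89.2 ± 2.46 against 131 ± 14.6 CPM) and the omega-hydroxylase gene Cyp4a10 (252 ± 133 against 804 ± 455 CPM). Acadl kept its call over the list in all 6 fits without 1 library, and Cyp4a10 lost it without dHEP-164, dHEP-165 or FF-158 (adjusted p = 0.15, 0.074 and 0.12). Markers of other cell types lay higher, with 0 passing over all genes or over the list alone. They were 10 Kupffer cell genes (median 0.42, adjusted p = 0.00046, and adjusted p = 0.68 with an estimated correlation), 12 endothelial genes (median 0.29, adjusted p = 0.013, and adjusted p = 0.73 with an estimated correlation) and 18 fibrosis genes (median 0.24, adjusted p = 0.045, and adjusted p = 0.96 with an estimated correlation). Of these the fibrosis list lost its call without dHEP-155 and FF-158 (adjusted p = 0.23). Female-biased genes lay lower (5 genes, median -2.69, adjusted p = 0.00059, and adjusted p = 0.57 with an estimated correlation) and male-biased genes higher (6 genes, median 1.89, adjusted p = 0.0039, and adjusted p = 0.68 with an estimated correlation), with 0 members passing in either list over all genes or over the list alone. Without dHEP-155 and FF-158 the female-biased list kept its call (median -1.23, adjusted p = 0.0058) and the male-biased list lost it (adjusted p = 0.9). Srebf1 stood at 279 ± 33.5 against 149 ± 56.9 CPM (log2 fold change 0.96 ± 0.40, adjusted p over the preset genes = 0.089, exact p = 0.1) and Lcn2 at 16.6 ± 14 against 31.5 ± 17.8 CPM (-0.98 ± 0.64, exact p = 0.2), with a dHEP mean of 8.53 CPM without dHEP-155 (-1.59 ± 0.64, adjusted p over the preset genes = 0.055). In chow tumors the unfolded protein response genes lay higher in dHEP (16 genes, median 0.28, adjusted p = 0.00067, and adjusted p = 0.56 with an estimated correlation). Dnajb9 was the 1 member passing over the list alone, 102 ± 11.5 against 54.4 ± 6.81 CPM (0.89 ± 0.25, adjusted p = 0.046), with 0 over all genes. It lost that call in 5 of 6 fits without 1 library, all but the one without dHEP-155 (adjusted p up to 0.16). Of the 14 lists called in chow tumors 11 lay lower in dHEP, each with 0 members passing over all genes or over the list alone. They included 10 Kupffer cell genes (median -0.91, adjusted p = 4.3e-06, and adjusted p = 0.56 with an estimated correlation) and 7 B and plasma cell genes (median -1.20, adjusted p = 5.4e-06, and adjusted p = 0.56 with an estimated correlation). The 10 T and NK cell genes had a median of -0.68 (adjusted p = 0.00039, and adjusted p = 0.57 with an estimated correlation) and the 7 MHC class II genes one of -1.02 (adjusted p = 9.8e-05, and adjusted p = 0.57 with an estimated correlation). The 15 Wnt and pericentral genes (median -1.08, adjusted p = 5.3e-06, and adjusted p = 0.56 with an estimated correlation) and the 19 tumor markers (median -1.11, adjusted p = 0.0064, and adjusted p = 0.57 with an estimated correlation) were lower as lists too. Lcn2 in chow tumors averaged 974 ± 1490 against 1180 ± 712 CPM (-1.92 ± 1.27, adjusted p over the preset genes = 0.38, exact p = 0.5). The dHEP mean rested on dHEP-155 at 2689 CPM, with dHEP-164 at 205.6 and dHEP-165 at 28.77 CPM. Without dHEP-155 it was 117.2 ± 125 CPM and Lcn2 passed over the preset genes (-3.62 ± 1.0, adjusted p = 0.02). The log2 fold change was -0.37 ± 1.09 without dHEP-165 and -2.64 ± 1.40 without FF-169. Over all genes 0 passed in chow tumors (378 at unadjusted p < 0.05 where chance alone gives 660, smallest adjusted p = 1). In chow non-tumor liver 0 passed too (588 where chance alone gives 633, smallest adjusted p = 0.61, for Lgals4).

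Averaged over both diets, dHEP against FF gave 0 genes in non-tumor liver (668 at unadjusted p < 0.05 where chance alone gives 633), with Il17ra at -0.96 ± 0.15 (adjusted p = 0.085). In tumors it gave 0 (403 at unadjusted p < 0.05 where chance alone gives 660). A model adding genotype to diet without their interaction called 2 genes in non-tumor liver, Il17ra (-0.97 ± 0.14, adjusted p = 0.035) and Cage1, a testis-restricted antigen gene (0.84 ± 0.12, adjusted p = 0.035). It called 0 in tumors (439 at unadjusted p < 0.05). These 2 models were chosen after the values had been seen. The genotype effect was not found to differ by diet for any gene. Dnajb9 had the smallest adjusted p in tumors (0.64, 653 genes at unadjusted p < 0.05 where chance alone gives 660). Slc1a2, a glutamate transporter, had it in non-tumor liver (0.21, 870 genes where chance alone gives 633). The genotype effect was not found to differ by tissue on alcohol either, where Myh11, smooth muscle myosin, had the smallest adjusted p (1, 266 genes at unadjusted p < 0.05 where chance alone gives 675).

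In FF non-tumor liver Cidec, Cidea, Plin4 and Cfd were higher on the alcohol diet than on chow, and Avpr1a, Agxt, Cth and Hal were lower. Cidec, a lipid droplet fusion protein, rose from 4.82 ± 1.6 CPM on chow (n = 3) to 66.8 ± 32.4 CPM (n = 4, log2 fold change 3.45 ± 0.42, adjusted p = 0.0098). Its relative Cidea rose from 0.655 ± 0.5 to 20.1 ± 14.5 CPM (3.32 ± 0.66, adjusted p = 0.042). The droplet coat gene Plin4 rose from 55.2 ± 24.5 to 161 ± 62 CPM (1.55 ± 0.29, adjusted p = 0.037). Cfd, the fat cell product adipsin, rose from 1.93 ± 2.22 to 62.2 ± 34.9 CPM (4.51 ± 0.63, adjusted p = 0.0098). Other rising genes were Wee1, a kinase restraining mitosis and a clock output (1.22 ± 0.214 to 9.47 ± 5.42 CPM) and Dio1, which activates thyroid hormone (83.5 ± 33.8 to 197 ± 27.8 CPM). The phosphate transporter Slc20a1 also rose (27.1 ± 8.86 to 63.6 ± 8.42 CPM), as did the proteoglycan Gpc1 (9.83 ± 3.85 to 41.4 ± 16.6 CPM). The largest falls were in Avpr1a, the hepatic vasopressin receptor (29.6 ± 11.7 to 6.76 ± 3.41 CPM), and Agxt, which detoxifies glyoxylate (235 ± 10.3 to 72.8 ± 26.5 CPM, -1.75 ± 0.23, adjusted p = 0.0098). Cth, the last enzyme of cysteine synthesis, fell from 515 ± 67.2 to 183 ± 65.3 CPM (-1.55 ± 0.24, adjusted p = 0.02). Hal, which breaks down histidine, fell too (402 ± 99.9 to 170 ± 61.8 CPM, adjusted p = 0.041). The prostaglandin transporter Slco2a1 fell from 70.9 ± 15.5 to 27.9 ± 6.06 CPM. Cyp2c54 fell from 389 ± 63.6 to 147 ± 60.6 CPM, although near-identical gene copies can share its reads. Without single libraries Cidec and Slco2a1 kept their calls in all 7 fits, and the other 12 genes of this paragraph lost theirs in 1 to 6, when a library other than FF-595 was left out (adjusted p up to 0.13). Without FF-595 the Cidea change was 3.99 ± 0.51, and without FF-157 mean Cfd on chow was 0.6969 CPM (5.10 ± 0.66, adjusted p = 0.018).

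In that comparison 73 genes passed BH over 12651 (32 higher and 41 lower on alcohol), 69 of them above 5 CPM in the higher group and with no overlap between groups. Of all tested genes 9.3% had no overlap, where chance gives 5.7%. Without FF-523 and FF-581 the count was 9, of which 4 were among the 73, and without FF-158 and dHEP-155, which stood apart in clock genes, it was 0. Leaving out any single library gave 3 to 216 genes, and 5 of 35 ways of splitting the same libraries gave as many genes, up to 510, so chance is not excluded.

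As a group in FF non-tumor liver, 24 cholesterol synthesis genes fell on alcohol (median -0.89, adjusted p = 1e-12, and adjusted p = 0.33 with an estimated correlation). Of these 1 passed over all genes, the sterol reductase Tm7sf2 (68.4 ± 16.4 to 26.7 ± 6.82 CPM), and 12 over the list alone. The 12 included Pmvk, phosphomevalonate kinase (31.8 ± 2.98 to 11.7 ± 5.08 CPM). Idi1, isopentenyl diphosphate isomerase, went from 135 ± 52 to 28.3 ± 19.6 CPM (-2.49 ± 0.54). The 14 lipid droplet and PPARg genes rose (median 1.13, adjusted p = 8.2e-08, and adjusted p = 0.29 with an estimated correlation). Over all genes 3 passed (Cidec, Plin4 and Cidea), and over the list alone 10 were higher. Plin5, a droplet coat protein of oxidative tissue, was the 1 member that fell over the list alone (72.7 ± 9.24 to 47 ± 10.7 CPM, -0.64 ± 0.17). The 10 genes of monocytes and recruited macrophages rose (median 0.83, adjusted p = 1e-05, and adjusted p = 0.33 with an estimated correlation), 1 over all genes and 7 over the list alone. That 1 was Trem2, a lipid-sensing macrophage receptor (0.29 ± 0.224 to 2.36 ± 0.9 CPM, 1.36 ± 0.26, adjusted p = 0.041). Over the list alone Spp1, osteopontin, also rose (22 ± 2.72 to 55.2 ± 32.7 CPM). The 10 Kupffer cell genes rose (median 0.64, adjusted p = 1e-05, and adjusted p = 0.46 with an estimated correlation), 0 over all genes and 5 over the list alone. Cd5l, a lipid-handling macrophage protein, stood at 186 ± 48.1 against 95.2 ± 49.3 CPM. The 16 cytochrome P450 and regulator genes fell (median -0.55, adjusted p = 8.2e-08, and adjusted p = 0.09 with an estimated correlation), 2 over all genes (Cyp2c54 and Cyp2c37) and 9 over the list alone. The 15 periportal genes fell (median -0.39, adjusted p = 6.9e-05, and adjusted p = 0.33 with an estimated correlation), 1 over all genes (Hal) and 5 over the list alone. The urea cycle enzyme Cps1 went from 6500 ± 383 to 4080 ± 824 CPM. The 15 interleukin-17 targets rose as a list (median 0.61, adjusted p = 0.0029, and adjusted p = 0.5 with an estimated correlation), with 0 passing over all genes or over the list alone. The 13 hepatocyte genes fell (median -0.26, adjusted p = 0.00026, and adjusted p = 0.12 with an estimated correlation), with 0 passing over all genes or over the list alone. The 14 tumor markers rose (median 0.68, adjusted p = 0.0016, and adjusted p = 0.71 with an estimated correlation), 0 over all genes and 1, Lcn2, over the list alone. The 18 fibrosis genes rose (median 0.27, adjusted p = 0.0016, and adjusted p = 0.71 with an estimated correlation), 0 over all genes and 6 over the list alone, among them the collagen genes Col1a1 and Col3a1. Without FF-523 and FF-581 the tumor marker (adjusted p = 0.55) and fibrosis lists (0.089) lost their call, the other lists named here kept theirs, and 10 of the 16 called lists did overall. Without single libraries Pmvk, Idi1 and Plin5 kept their calls over the list in all 7 fits. Spp1 and Cd5l lost theirs without FF-523, FF-581, FF-157 or FF-159 (adjusted p up to 0.2) and Cps1 without FF-159 (0.058). Over all genes Tm7sf2, Cyp2c37 and Trem2 lost theirs in 3, 5 and 6 of the 7, none of them without FF-595, and without FF-158 mean Trem2 on chow was 0.1637 CPM.

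In dHEP non-tumor liver cholesterol synthesis genes also fell on alcohol. Idi1 went from 135 ± 42.8 CPM (n = 3) to 13.6 ± 3.53 CPM (n = 4, -3.20 ± 0.54, adjusted p = 0.023). Fdps, farnesyl diphosphate synthase, went from 223 ± 69.9 to 30.6 ± 6.94 CPM (-2.80 ± 0.43, adjusted p = 0.023). Cyp51, lanosterol demethylase, went from 163.8 ± 47.4 to 26.2 ± 7.09 CPM (-2.60 ± 0.43, adjusted p = 0.023). The core clock gene Arntl fell from 19.4 ± 16.4 to 1.65 ± 0.552 CPM (-2.69 ± 0.48, adjusted p = 0.028). Wee1 rose from 1.86 ± 0.886 to 14.6 ± 3 CPM (2.48 ± 0.38, adjusted p = 0.023). Plin4 rose from 53.8 ± 12.6 to 186 ± 23.7 CPM (1.79 ± 0.29, adjusted p = 0.023) and Nr1i3 from 157.5 ± 31.2 to 433.1 ± 164.3 CPM (1.40 ± 0.27, adjusted p = 0.038). Por rose from 177 ± 38.4 to 393 ± 69.9 CPM (1.15 ± 0.21, adjusted p = 0.033). Vnn1, a PPARa-regulated pantetheinase, rose from 63.8 ± 14.3 to 145 ± 29.1 CPM (1.17 ± 0.21, adjusted p = 0.028). None of these 9 genes kept its call in all 7 fits without 1 library. Each lost it in 3 to 7 of them, and each library ended calls when left out (adjusted p up to 0.18). Without dHEP-155 mean Arntl on chow was 9.96 ± 0.3703 CPM (-2.07 ± 0.43, adjusted p = 0.13).

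As lists, 24 cholesterol synthesis genes lay lower on alcohol in dHEP non-tumor liver (median -1.60, adjusted p = 1.8e-23, and adjusted p = 0.38 with an estimated correlation, 10 over all genes and 21 over the list alone). Fatty acid oxidation lay higher (22 genes, median 0.37, adjusted p = 1.6e-13, and adjusted p = 0.38 with an estimated correlation), 1 over all genes, Vnn1, and 8 over the list alone. These included the acyl-CoA dehydrogenase gene Acadm (284 ± 12.5 to 367 ± 27.8 CPM) and the thioesterase gene Acot1 (21.5 ± 2.14 to 53.9 ± 11.8 CPM). Cpt1a, which imports fatty acids into mitochondria, was also among them (430 ± 18.5 to 605 ± 93.3 CPM). The 14 lipid droplet and PPARg genes lay higher (median 0.55, adjusted p = 3.2e-07, and adjusted p = 0.49 with an estimated correlation). Only Plin4 passed over all genes, and 2 over the list alone (Plin4 and Cidec, 10 ± 1.96 to 37.5 ± 19.4 CPM). The unfolded protein response lay lower (16 genes, median -0.39, adjusted p = 0.0068, and adjusted p = 0.95 with an estimated correlation), 0 over all genes and 6 over the list alone. The chaperone Calr went from 873 ± 63.8 to 515 ± 102 CPM. The 16 Wnt and pericentral genes lay higher (median 0.19, adjusted p = 0.0045, and adjusted p = 0.95 with an estimated correlation), 1 over all genes and over the list alone, Slc1a2. The 15 periportal genes lay lower (median -0.44, adjusted p = 0.021, and adjusted p = 0.95 with an estimated correlation), 0 over all genes and 2 over the list alone, Hal and Arg1. Cidec and Calr lost their call over the list without dHEP-164 (adjusted p = 0.055 and 0.056). Acadm, Acot1 and Cpt1a lost theirs in 4 to 6 of the 7 fits without 1 library, none of them the one without dHEP-549 (up to 0.099).

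Of 12651 genes 83 passed BH (24 higher, 59 lower), 78 of them above 5 CPM and without overlap. Higher genes made up 28.9% of the calls, against 51.3% after between-library scaling. Without dHEP-155 and FF-158 the count was 6, of which 4 were among the 83, and leaving out single libraries gave 2 to 42. Of 35 splits of the libraries only the real one reached 83, the highest other giving 1. The FF and dHEP comparisons share no libraries, and 5 genes were higher in both (Fam102a, Plin4, Pmm1, Vnn1 and Wee1, 0.0607 expected by chance, Fisher's exact p = 3.1e-09). In both 13 were lower, including Agxt, Avpr1a, Cbs, Clock, Cth, Gcat and Tm7sf2 (0.191 expected, Fisher's exact p = 1.9e-21). Fisher's test takes genes as independent and ignores the shared spread, so these p-values are too small. A difference between cohorts would also be shared by both comparisons. Across all genes the log2 fold changes of the 2 comparisons correlated at r = 0.42.

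**Figure D2:**
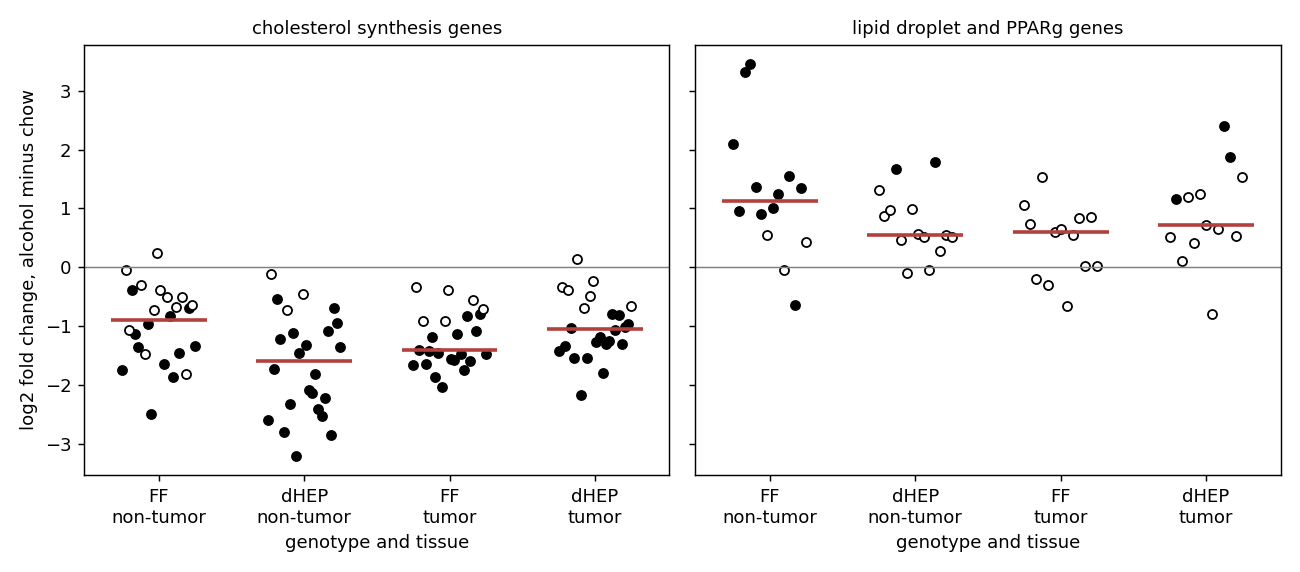
Log2 fold change, alcohol minus chow, of each cholesterol synthesis gene and each lipid droplet and PPARg gene in 4 comparisons; filled dots passed BH over the list alone and the red line is the median. Cholesterol synthesis medians were -0.89 (FF non-tumor), -1.60 (dHEP non-tumor), -1.41 (FF tumor) and -1.05 (dHEP tumor).

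In tumors of FF mice the cholesterol synthesis genes were again lower on alcohol (24 genes, median -1.41, adjusted p = 5.8e-26, and adjusted p = 0.11 with an estimated correlation), 0 passing over all genes and 18 over the list alone. Among them were Nsdhl, a sterol dehydrogenase (41.4 ± 8.24 CPM on alcohol, n = 4, against 154 ± 86 CPM on chow, n = 3, -1.74 ± 0.34) and Fdft1, squalene synthase (77.3 ± 17.6 against 262 ± 133 CPM). Lymphocyte genes were lower on alcohol. The 7 B and plasma cell genes had a median of -1.79 (adjusted p = 1.4e-09, and adjusted p = 0.11 with an estimated correlation), 0 over all genes and 6 over the list alone. The antibody joining chain Jchain stood at 29.3 ± 26.4 against 512 ± 324 CPM (-4.22 ± 0.92). The 10 T and NK cell genes had a median of -1.30 (adjusted p = 4.5e-09, and adjusted p = 0.3 with an estimated correlation), 0 over all genes and 9 over the list alone. Cd8a, the co-receptor of cytotoxic T cells, stood at 1.16 ± 0.657 against 9.04 ± 8.73 CPM. Cd8a lost its call over the list in 5 of 7 fits without 1 library (FF-503, FF-581, FF-595, FF-167 or FF-169, adjusted p up to 0.26). Its chow mean was 4.422 CPM without FF-169 (-0.99 ± 0.69), and without FF-168 the change was -2.65 ± 0.60. Nsdhl, Fdft1 and Jchain kept theirs, with Jchain on alcohol at 17 CPM without FF-503 and its change -4.92 ± 0.99 without FF-168. Of the 12 called lists 7 were lower, among them 25 proliferation genes (median -0.69, adjusted p = 3.1e-05, and adjusted p = 0.75 with an estimated correlation). The 16 unfolded protein response genes were higher (median 0.42, adjusted p = 2.3e-06, and adjusted p = 0.11 with an estimated correlation). Both had 0 members passing over all genes or over the list alone. Over all 13205 genes 0 passed, with 718 at unadjusted p < 0.05 where chance alone gives 660, and the smallest adjusted p was 0.68, for the eosinophil granule gene Prg2.

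In dHEP tumors 1441 genes differed between diets at unadjusted p < 0.05, where chance alone gives 660. Of 13205 genes only Hsd3b2, a steroid dehydrogenase, passed (1.99 ± 0.26, adjusted p = 0.034). It rose from 5.14 ± 0.989 CPM on chow (n = 3) to 23.9 ± 6.45 CPM on alcohol (n = 4). Fatty acid oxidation genes lay higher on alcohol (22 genes, median 0.69, adjusted p = 1.6e-15, and adjusted p = 0.077 with an estimated correlation), 0 over all genes and 6 over the list alone. The peroxisomal enzyme gene Ehhadh stood at 208 ± 55 against 80.5 ± 38 CPM (1.42 ± 0.28) and Acot1 at 16.1 ± 10.7 against 1.51 ± 0.765 CPM. Cholesterol synthesis lay lower (24 genes, median -1.05, adjusted p = 3.2e-12, and adjusted p = 0.34 with an estimated correlation), 0 over all genes and 17 over the list alone. Mvd, mevalonate decarboxylase, stood at 15 ± 1.76 against 55.6 ± 12.9 CPM (-1.80 ± 0.31) and Hmgcs1, an early enzyme of the pathway, at 280 ± 156.6 against 1120 ± 272 CPM. The 13 lipid droplet and PPARg genes lay higher (median 0.71, adjusted p = 4e-07, and adjusted p = 0.077 with an estimated correlation), 0 over all genes and 3 over the list alone. These included Plin4 (54.8 ± 29.4 against 9.12 ± 4.31 CPM, 2.40 ± 0.55) and Plin5 (42.7 ± 23.7 against 9.65 ± 2.54 CPM). The 16 cytochrome P450 and regulator genes lay higher (median 0.26, adjusted p = 0.0024, and adjusted p = 0.41 with an estimated correlation), 0 over all genes and 3 over the list alone. Among them were Por (214 ± 49.6 against 79.1 ± 33.1 CPM) and Nr1i3 (78.8 ± 51.8 against 10.2 ± 5.66 CPM). Cell-type and zonation lists lay higher as well, with 0 members passing over all genes or over the list alone. These were 15 Wnt and pericentral genes (median 0.78, adjusted p = 5.5e-06, and adjusted p = 0.35 with an estimated correlation), 13 hepatocyte genes (median 0.17, adjusted p = 0.0024, and adjusted p = 0.35 with an estimated correlation) and 10 Kupffer cell genes (median 0.50, adjusted p = 0.0017, and adjusted p = 0.65 with an estimated correlation). Without tumor dHEP-549, which lay between the tissues, 11 of the 12 called lists remained and the Kupffer cell list lost its call (adjusted p = 0.061). The 8 members named as passing over their lists kept those calls in all 7 fits without 1 library. The Hsd3b2 call was lost in fits without tumor dHEP-520, dHEP-549, dHEP-550, dHEP-155 or dHEP-165, with 1 other gene called without dHEP-550, and without dHEP-164 the count was 53. Among ways of splitting the libraries 6 of 35 called at least 1 gene, up to 263, so chance is not excluded.

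Tumors and non-tumor liver differed widely in each of the 4 diet and genotype groups. In FF mice on alcohol Ccnd1, cyclin D1, rose from 24.7 ± 11.2 to 162 ± 26.5 CPM (n = 4 each, log2 fold change 2.75 ± 0.27, adjusted p = 8.1e-07). Gpc3 rose from 12.1 ± 11.6 to 169.2 ± 56.1 CPM (4.27 ± 1.26, adjusted p = 0.015). Psat1, an enzyme of serine synthesis, rose from 5.15 ± 7.39 to 55.5 ± 21.7 CPM (3.80 ± 0.58, adjusted p = 5.6e-05), and the surface protein Ly6d from 29.2 ± 22.6 to 388 ± 190 CPM. The dense-core vesicle protein Hid1 rose from 4.93 ± 4.29 to 62.1 ± 15.7 CPM (3.64 ± 0.35, adjusted p = 8.1e-07), and the cell cycle inhibitor Cdkn2b rose from 2.49 ± 3.18 to 32.6 ± 8.12 CPM (adjusted p = 0.0013). Cyp2e1, the ethanol-oxidising cytochrome, fell from 6160 ± 468 to 699 ± 441 CPM (-3.64 ± 0.49, adjusted p = 1.6e-05). Etnppl, which breaks down phosphoethanolamine, fell from 81.3 ± 50.1 to 3.68 ± 2.21 CPM (adjusted p = 0.00019). Cfd fell from 62.2 ± 34.9 to 1.24 ± 1.2 CPM (-4.76 ± 0.52, adjusted p = 1.8e-06) and Slc27a5 from 728 ± 37.2 to 201 ± 19.3 CPM (-1.86 ± 0.20, adjusted p = 1e-06). The major urinary protein gene Mup7 fell from 10800 ± 9970 to 575 ± 532 CPM and Cyp2c54 from 147 ± 60.6 to 8.12 ± 5.31 CPM, although near-identical copies in both families can share reads. Gpc3 lost its call without non-tumor liver FF-595 (3.60 ± 1.34, adjusted p = 0.06). Ly6d lost it without tumor FF-523 or FF-595 (0.059 and 0.055) or non-tumor liver FF-503 or FF-595 (0.05 and 0.095, the last at 3.29 ± 1.37). Mup7 lost it without tumor FF-581 (-3.36 ± 1.55, adjusted p = 0.13) or non-tumor liver FF-503 (0.077) or FF-595 (0.084), where the mean was 6734 CPM. The Mup7 tumor mean was 342.2 CPM without FF-595 (-5.65 ± 1.70). Without non-tumor liver FF-581 the non-tumor means of Psat1, Hid1 and Cdkn2b were 1.485, 2.9 and 0.9525 CPM, with Psat1 at 4.52 ± 0.50, and without FF-523 that of Gpc3 was 7.497 CPM. Without tumor FF-581 Cyp2e1 changed by -2.79 ± 0.28 and Cyp2c54 by -3.62 ± 0.58, and without tumor FF-523 mean Cfd was 0.748 CPM. Of 13503 genes 3315 passed (1879 higher and 1436 lower in tumors).

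In FF mice on chow, tumor and non-tumor liver came from different animals. Afp rose from 4.35 ± 1.6 to 656 ± 697 CPM (n = 3 each, 6.35 ± 1.35, adjusted p = 0.0012), and the adhesion gene Cdh17 from 0.154 ± 0.139 to 103 ± 48.2 CPM (6.38 ± 1.4, adjusted p = 0.0016). Gpc3 rose from 6.35 ± 8 to 309 ± 213 CPM (adjusted p = 0.0059), and Psat1 from 0.904 ± 0.798 to 71.1 ± 43.5 CPM (adjusted p = 1.5e-05). Cyp2f2, a periportal cytochrome, fell from 720 ± 283 to 60.8 ± 61.1 CPM (adjusted p = 0.0021) and Cyp4a10 from 804 ± 455 to 58.1 ± 53.4 CPM (adjusted p = 0.00024). All 6 kept their calls without any 1 library, but several means rested on 1. Non-tumor Gpc3 was 15.58 CPM in FF-158 and averaged 1.731 ± 0.2322 CPM without it (6.43 ± 1.61, adjusted p = 0.0051), and non-tumor Psat1 averaged 0.4496 CPM without FF-158. Without tumor FF-168 mean Afp was 259.5 ± 178.5 CPM (5.46 ± 1.48) and Cyp4a10 30.66 CPM (-5.18 ± 0.77). Without tumor FF-169 mean Cyp2f2 was 27.59 CPM (-5.12 ± 1.0), with Afp at 7.17 ± 1.49 and Gpc3 at 6.42 ± 1.61. Without tumor FF-167 Cyp2f2 changed by -3.09 ± 0.95 and Cyp4a10 by -3.19 ± 0.68, and without non-tumor FF-157 mean Cdh17 was 0.07491 CPM. Here 4153 genes passed (2864 higher, 1289 lower). Of the called genes 69% were higher, and 53.3% after between-library scaling. The median over all genes was 0.16 here and 0.145 in dHEP on chow, and 0.009 and 0.023 after scaling.

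In dHEP mice on alcohol Ccnd1 rose from 20.9 ± 2.13 to 221 ± 39.6 CPM (n = 4 each, 3.33 ± 0.27, adjusted p = 1e-07). The glial adhesion protein gliomedin, Gldn, rose from 3.1 ± 1.39 to 122 ± 23.9 CPM (4.95 ± 0.62, adjusted p = 1.5e-05), and the adhesion molecule Igdcc4 from 0.561 ± 0.295 to 51.2 ± 29 CPM (4.83 ± 0.54, adjusted p = 3.4e-06). Sqle, squalene epoxidase, rose from 6.93 ± 3.8 to 123 ± 15.6 CPM (4.09 ± 0.61, adjusted p = 8.1e-05). Cyp2e1 fell from 8410 ± 847 to 1140 ± 576 CPM (-3.02, adjusted p = 2e-04). In all 2754 genes passed (1736 higher, 1018 lower, 63% higher, and 49.5% after scaling). With tumor and non-tumor liver of an animal fitted as a block, in these 2 groups only, 1601 passed, 1481 of them shared. The same 2 groups without the block gave 1764. On chow, dHEP tumors held Gpc3 at 212 ± 223 against 1.53 ± 0.976 CPM (n = 3 each, 5.52 ± 1.45, adjusted p = 0.0067) and Psat1 at 57.8 ± 9.19 against 0.784 ± 0.219 CPM (adjusted p = 1.3e-05). Without tumor dHEP-155 mean Gpc3 was 91.09 ± 106.1 CPM and its call was lost (4.49 ± 1.59, adjusted p = 0.053), and without dHEP-165 the change was 6.86 ± 1.53. The proliferation antigen Mki67 stood at 116 ± 31 against 8.1 ± 3.04 CPM (3.69 ± 0.64, adjusted p = 2e-04) and Cyp2e1 at 336 ± 66.4 against 6130 ± 599 CPM (-4.20, adjusted p = 1.6e-05). There 3769 genes passed (2328 higher, 1441 lower, 61.8% higher, and 49.1% after scaling). With the animal as a block, in these 2 groups only, 2149 passed, 2000 of them shared. The same 2 groups without the block gave 1925.

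In all 4 groups 906 genes were higher in tumors (8.83 expected if the groups were independent) and 624 lower (1.1 expected). The 4 comparisons share 1 fit and its spread for each gene. They are thus not independent, and the expected figures are too small. Cholesterol synthesis genes higher in all 4 included Srebf2, Mvk, Mvd, Fdps, Sqle, Lss, Cyp51 and Dhcr7, and proliferation genes included Mki67, Top2a, Ccna2, Ccnb1 and Cdk1. Of the MAPK and DEN-tumor signalling genes Dusp4, Dusp5, Dusp6, Spred1 and Ccnd1 were higher in all 4. Of tumor markers Golm1, Ly6d, Prom1, Lcn2, Scd2 and Akr1c18 were, the last with near-identical copies. Genes of alcohol metabolism lower in all 4 were Adh4, Adh5, Aldh2, Aldh1a1, Aldh3a2, Cyp2e1 and Cat. Pericentral genes lower in all 4 were Glul, Oat, Slc1a2, Nkd1, Notum, Cyp2e1 and Cyp1a2. Log2 fold changes of FF and dHEP tumors, which share no libraries, correlated across genes at r = 0.88 on alcohol and 0.87 on chow.

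Of 34 lists 16, 20, 13 and 15 were called, and values of 6 follow, for FF alcohol, FF chow, dHEP alcohol and dHEP chow in turn. The 25 proliferation genes rose in tumors by medians of 1.0, 2.2, 1.84 and 2.12 (adjusted p = 2.9e-05, 1.2e-09, 3.9e-12 and 4.9e-09, and adjusted p = 0.58, 0.48, 0.3 and 0.41 with an estimated correlation). Over all genes 14, 23, 23 and 22 were higher, and 21, 23, 23 and 22 over the list alone. Tk1, thymidine kinase, was lower over all genes in dHEP alcohol, a call lost in 6 of 8 fits without 1 library (all but dHEP-550 of either tissue, adjusted p up to 0.15), and over the list alone in dHEP alcohol and dHEP chow (lost there in 2 of 6). The 24 cholesterol synthesis genes rose by 1.11, 1.31, 1.74 and 1.16 (adjusted p = 0.00012, 0.00033, 4.7e-12 and 0.00059, and adjusted p = 0.58, 0.5, 0.3 and 0.67 with an estimated correlation). Higher members numbered 13, 14, 21 and 14 over all genes and 16, 16, 21 and 16 over the list alone. In FF alcohol 1, Ebp, was lower over the list alone, a call lost in 4 of 8 fits without 1 library (adjusted p up to 0.059). The 15 MAPK and DEN-tumor signalling genes rose by 1.4, 1.01, 0.94 and 1.1 (adjusted p = 0.00026, 0.02, 5.8e-05 and 0.002, and adjusted p = 0.4, 0.5, 0.3 and 0.44 with an estimated correlation). Of these 11, 7, 8 and 7 were higher over all genes and 11, 8, 8 and 7 over the list alone. Phlda1 was lower over the list alone in FF alcohol and FF chow, calls lost in 4 of 8 and 5 of 6 such fits (adjusted p up to 0.14 and 0.13). The 16 cytochrome P450 and regulator genes fell (medians -2.35, -2.41, -1.85 and -1.91, adjusted p = 2.3e-09, 6.1e-10, 3.6e-10 and 1.2e-09). Lower members numbered 11, 14, 9 and 12 over all genes and 12, 14, 11 and 12 over the list alone. In FF chow 1, Cyp1a1, was higher over the list alone, a call lost in 3 of 6 such fits (without tumor FF-168, non-tumor FF-158 or non-tumor FF-159). Its tumor mean rested on FF-168 (8.80 ± 12.8 CPM, and 1.404 ± 0.2846 CPM without it, adjusted p = 0.77). The list as a whole kept its call with an estimated correlation in FF alcohol, FF chow and dHEP chow (adjusted p = 0.044, 0.039 and 0.038) and lost it in dHEP alcohol (adjusted p = 0.075 with an estimated correlation). The 18 bile acid genes behaved alike (medians -1.73, -2.02, -1.07 and -1.92, adjusted p = 1.5e-08, 1.4e-09, 2.2e-07 and 4.9e-09, and adjusted p = 0.044, 0.039, 0.089 and 0.038 with an estimated correlation). Here 12, 13, 10 and 14 were lower over all genes and 12, 14, 11 and 14 over the list alone. In dHEP chow 1 member was higher over all genes and over the list alone, the exporter gene Abcc4 (7.71 ± 2.19 to 93.3 ± 91.5 CPM). That call was lost in 5 of 6 fits without 1 library, all but tumor dHEP-164 (3.88 ± 0.95), and without tumor dHEP-155 the tumor mean was 44.87 CPM (1.69 ± 1.03, adjusted p = 0.28). The 10 alcohol metabolism genes fell (medians -1.32, -1.3, -0.97 and -1.23, adjusted p = 1.1e-05, 2.6e-05, 0.00031 and 7.5e-06, and adjusted p = 0.058, 0.081, 0.21 and 0.055 with an estimated correlation). In each group 7 were lower over all genes, and 7, 7, 7 and 8 over the list alone. Over the list alone 1 was higher in each group, the acetyl-CoA synthetase gene Acss1 in FF alcohol, FF chow and dHEP chow and the aldehyde dehydrogenase gene Aldh1b1 in dHEP alcohol. Over all genes 0, 1, 0 and 0 were higher, the 1 being Acss1, and that call held in all 6 fits without 1 library. Aldh1b1 lost its call over the list without tumor dHEP-550 (mean 107 against 212.4 CPM, 1.16 ± 0.65, adjusted p = 0.11). Acss1 lost its call over the list in 5 of 8 such fits in FF alcohol and 3 of 6 in dHEP chow, where the tumor mean was 0.5329 CPM without dHEP-155 (adjusted p = 0.22).

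**Figure D3:**
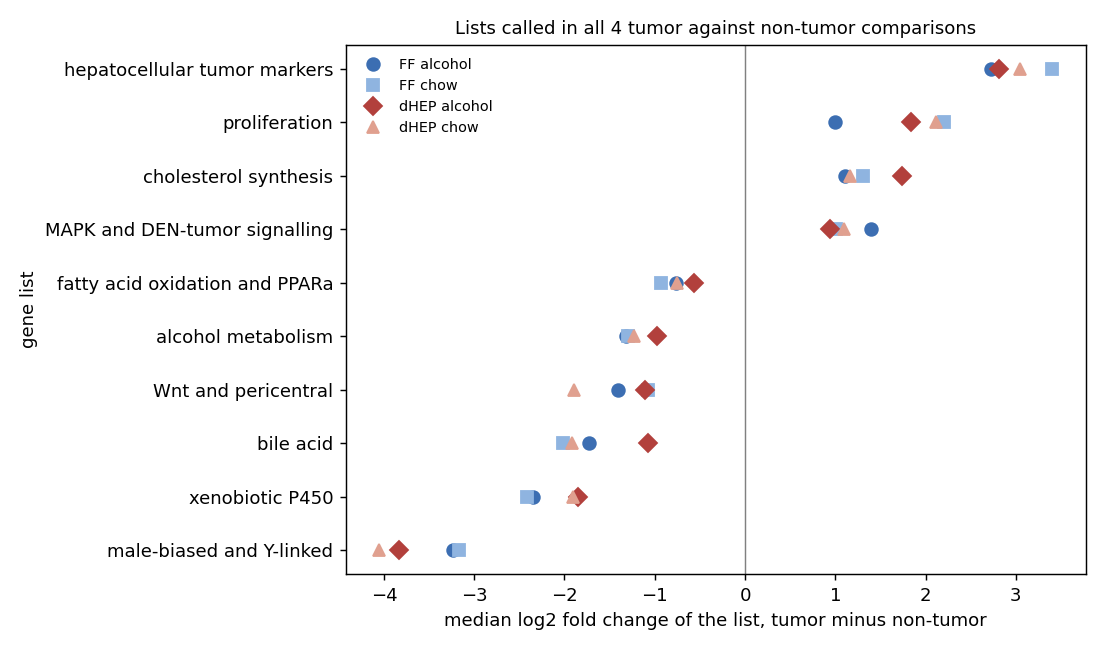
Median log2 fold change, tumor minus non-tumor, of 10 gene lists, with a marker for each diet and genotype group. Medians for proliferation ran from 1.0 to 2.2 and for cytochrome P450 and regulators from -2.41 to -1.85.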

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

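The tests on the tumor genes in mice FF-523 and FF-581 were chosen only after the result was seen. Of 129 checks for a library far from the 3 others of its group 7 gave one, where chance gives 6.4, so their number was about that of chance. In dHEP alcohol non-tumor liver, Srebf2 was 19.88 CPM in mouse dHEP-518 against 17.32 to 17.43 in the others, and genes at 1 CPM or more numbered 11890 in mouse dHEP-549 against 12080 to 12100. In dHEP alcohol tumors Dhcr7 was 157.1 CPM in mouse dHEP-550 against 49.81 to 57.82. In FF alcohol non-tumor liver Slc20a1 was 51.02 CPM in mouse FF-595 against 66.65 to 68.48, Cyp2c54 was 237.3 CPM in mouse FF-503 against 108.2 to 126.5, Vmn2r3 was 0.5932 CPM in mouse FF-581 against 0 to 0, and Psat1 was 16.15 CPM in mouse FF-581 against 0.7044 to 2.761.

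Wee1 differed in direction between groups: it was higher in the tumor than in non-tumor liver in 3 of 3 dHEP mice on chow (mean log2 difference 1.16 ± 0.94) and in 0 of 4 dHEP mice on alcohol (-0.25 ± 0.19). In FF mice on alcohol it was higher in 1 of 4 (-0.23 ± 0.51). The difference was not tested, and 64 genes were looked through for such a case.

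The non-tumor libraries of mice FF-523 and FF-581 held tumor genes at raised levels: of 238 genes chosen from the chow mice, 225 and 235 were higher than in the other FF alcohol non-tumor libraries (median log2 excess 0.87 and 1.13). If tissue of the sampled tumor of the same animal were mixed in, the excess should resemble that tumor best; it did in 2 of 2 libraries, though by margins of only 0.51 against 0.50 and 0.77 against 0.73 in r, so some tumor tissue in both samples is a hypothesis. Of 202 and 187 genes compared, 0.5% exceeded the level in that tumor (median 13.1% and 22.4% of it), which decides nothing, since those genes were chosen for a high level in it. A further small lesion elsewhere in the liver stays open and was not tested, nor was any biological difference between these animals and mice FF-503 and FF-595.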

How the results depend on the processing

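The alternatives that leave out 2 libraries together, retest the lists without tumor dHEP-549 or pool both diets were tests chosen only after the result was seen. Of the single-gene values 758 kept their direction and stayed called or uncalled, 83 were weaker, 2 stronger and 17 reversed. These labels compare direction and call only, weaker standing for a lost call, so the size of a value could change under any of them. Without single libraries 629 were the same in this sense, 18 reversed and the rest weaker. All of the reversed were among Srebf1, Srebf2, Dhcr7 and Casp2, which passed no adjusted test. Of the counts, 98 stayed and 33 moved, and 103 and 25 without single libraries. The cause was not tested unless stated. Median-of-ratios scaling gave 153 genes for FF diet in non-tumor liver, and it turned no called list, while 15 of 17 list calls remained for genotype in tumors on alcohol, 11 of 14 in tumors and 13 of 15 in non-tumor liver on chow, and 13 of 15 for tissue in dHEP chow; no list named in the report lost its call. Sample quality weights gave 402 there, 568 for dHEP diet in non-tumor liver, 26 for FF diet and 0 for dHEP diet in tumors, and 1 for genotype on chow in non-tumor liver. With no filter on low values, and so more genes tested, FF diet in non-tumor liver gave 31 and dHEP diet in tumors 0. With the 2 compared groups only, and so fewer samples, FF diet gave 1 and dHEP diet 197 in non-tumor liver, dHEP diet in tumors 0, and tissue 1764 in dHEP alcohol and 1925 in dHEP chow. With the animal as a block, in the compared groups only, tissue gave 1601 in dHEP alcohol and 2149 in dHEP chow. The same groups without the block gave 1764 and 1925, so the fall from the main counts came mostly with the smaller fit. The block fit ended no list call and moved no other count beyond 1.5 times. No paired analysis was possible for FF chow because the numbers of its tumor and non-tumor mice differ. The additive genotype and diet model, with 1 genotype effect for both diets, gave 2 in non-tumor liver. Without FF alcohol non-tumor libraries FF-523 and FF-581, and so with fewer samples, FF diet gave 9 and 9 lists were called for genotype; without dHEP-155 and FF-158, FF diet gave 0 and dHEP diet 6. Of the called lists of FF diet 10 of 16 and 14 of 16 remained, and 9 of 15 for genotype on chow. Without tumor dHEP-549, 12 of 17 remained for genotype on alcohol in tumors, 11 of 12 for dHEP diet in tumors and 12 of 13 for tissue in dHEP alcohol. With an estimated correlation 0 lists were called in the genotype comparisons (alcohol tumor 0, alcohol non-tumor 0, chow tumor 0, chow non-tumor 0) and in the diet comparisons (FF 0 and 0, dHEP 0 and 0), and 2, 2, 0 and 2 for tissue in FF alcohol, FF chow, dHEP alcohol and dHEP chow, against 6 to 21 with the preset correlation. Without single libraries, genotype on chow gave 0 to 4 genes in tumors and 0 to 1 in non-tumor liver, FF diet in non-tumor liver 3 to 216, dHEP diet 0 to 53 in tumors and 2 to 42 in non-tumor liver, dHEP chow tissue 2372 to 4234, genotype by diet in tumors 0 to 2 and genotype by tissue 0 to 1; the other tissue counts ran from 2016 to 3938. Reversed values were, on alcohol in tumors, Dhcr7 -0.03 with weights and Casp2 -0.04 averaged over diets and -0.02 additive; in non-tumor liver Casp2 0.03 with scaling, 0.04 averaged, 0.03 additive and 0.34 without FF-523 and FF-581, Srebf1 0.42 averaged, 0.34 additive and 0.16 without FF-523 and FF-581, and Dhcr7 0.00 without FF-523 and FF-581. On chow in tumors they were Dhcr7 0.00 with scaling, 0.03 averaged and 0.03 additive, and Srebf2 -0.14 with weights, -0.07 averaged and -0.08 additive. Without single libraries, values that reversed ran in alcohol tumors from -0.01 to 0.16 (Casp2) and -0.32 to 0.27 (Dhcr7), in alcohol non-tumor liver from -0.19 to 0.15 (Casp2) and -0.55 to 0.12 (Srebf1), in chow tumors from -0.37 to 0.33 (Srebf2), -0.46 to 0.09 (Casp2) and -0.24 to 0.25 (Dhcr7), and in chow non-tumor liver from -0.27 to 0.30 (Dhcr7) and -0.07 to 0.25 (Casp2). Sex as a covariate was not run since the labels give no sex and Xist and Y genes were not analysed here, and count models were not run since the values are CPM. Depth limits genes near 1 CPM, where a value rests on 9.57 to 17.82 reads.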

Other observations

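The tests on clock genes and on female-biased genes were chosen only after the result was seen; the counts over other splits of the samples were planned. Albumin mRNA made up 6.78% to 14.45% of the CPM in tumors (median 10.17%) and 2.43% to 6.41% in non-tumor liver (median 3.98%), so the secreted protein genes moved apart in tumors, with Alb higher in share while the Mup genes fell. In FF chow tumors, lists of immune and scar cells were raised over non-tumor liver: monocyte genes (11; median 1.75; list test adjusted p = 0.0011, and 0.5 with an estimated correlation; 8 over all genes and 11 over the list alone), B and plasma cell genes (7; 1.8; 0.0028, and 0.49; 5 and 6), T and NK cell genes (10; 1.31; 0.0045, and 0.5; 8 and 10) and fibrosis genes (21; 1.49; 0.00023, and 0.5; 12 and 14). Of these genes Col3a1, Col4a1 and Acta2 (fibrosis) and Cd9 (monocyte) were higher over all genes in tumors of all 4 groups, so their rise was not particular to FF chow. Kupffer cell genes fell in tumors of FF alcohol (median -1.15, adjusted p = 0.00066, and 0.5 with an estimated correlation), dHEP alcohol (-1.16, 0.00016, and 0.46) and dHEP chow mice (-1.88, 2e-05, and 0.41), with no call in FF chow (-0.12, 0.35).

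The alcohol tumor dHEP-549 lay between the tissues on the first principal component, which held 50.3% of the variance: -5.1, with the other tumors at 18.5 to 77.7 and non-tumor liver at -53.4 to -17.1. It held Afp at 5.47 and Gpc3 at 0.473 CPM, and Il17ra at 8.38 CPM. No cause was tested.

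Core clock gene Arntl was 38.4 CPM in dHEP chow non-tumor liver dHEP-155 and 33.2 CPM in FF chow non-tumor liver FF-158, against 9.70 to 15.5 in the other chow and 1.06 to 7.38 in the alcohol non-tumor libraries; the clock output Dbp was 1.56 and 1.22 CPM in those 2. If the clock phase of the animal at collection set these levels, tumor and non-tumor liver of an animal should deviate together: over 11 pairs r was 0.84 (exact one-sided p = 0.043 by 3456 permutations; Spearman rho 0.76, exact p = 0.048), and 0.84 without the 2 farthest pairs. Any factor shared by the 2 samples of an animal would give such agreement, so the test cannot single out clock phase, which stays a hypothesis. FF-158 is in none of the pairs, since the FF chow numbers differ between tissues. Collection time is not given in the sources used here and cannot be told apart from diet and cohort. The falls of Arntl and Clock and the rise of Wee1 on alcohol may reflect it as well. On alcohol an index, the mean log2 of Arntl, Npas2 and Clock minus that of Dbp, Per2, Per3 and Tef, was lower in dHEP. In tumors it ran from -4.29 to -3.72 in dHEP and from -3.37 to 0.47 in FF. In non-tumor liver it overlapped, at -4.1 to -3.46 and -3.64 to -1.72. Collection time may thus bear on the genotype comparisons on alcohol too, which was not tested.

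FF chow non-tumor liver FF-158 held liver genes usually higher in females, Cyp3a41a at 374 CPM and A1bg at 131 CPM, and the male-biased Mup20 at 157.4 CPM and Hsd3b5 at 0.503 CPM. In the other chow non-tumor libraries Cyp3a41a reached 2.999 CPM, A1bg 1.12 CPM, and Mup20 was at least 3668 CPM. For a female animal, the 4 X-linked genes that escape inactivation stood 0.96 SDs above the mean of the other 13 non-tumor libraries, too little to decide. Library FF-158 shares its clock shift with dHEP chow non-tumor library dHEP-155. From the other 4 chow libraries, 11 sex-biased genes deviated by a median log2 of 5.11 ± 1.87 in FF-158 and 0.50 ± 0.60 in dHEP-155 (SD over genes). This argues against the shift as the whole cause but cannot exclude it, as it sets 1 library against 1. Tumor FF-168, with Arntl at 53.8 CPM, held Cyp3a41a at 28.91, A1bg at 9.594 and Mup20 at 301.7 CPM. In tumor dHEP-155, with Arntl at 36.98 CPM, the same genes stood at 0.6194, 0.2978 and 4754 CPM. A part of the shift stays open, since 2 of 5 female-biased genes were higher in dHEP-155 than in each of the other 4, against 5 of 5 in FF-158. So does a female animal.

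Other splits of the same libraries tested whether chance gives such counts. For dHEP diet in non-tumor liver only the real split was as large (83 genes, 1 of 35 splits, highest other 1). That is the smallest share 35 splits can give, and the other comparisons were split alike, so chance is not excluded. Leaving out single libraries gave 2 to 42 genes there. For tissue the numbers pair the samples, and the splits that part as many pairs of an animal's samples are 8 in each alcohol group and 4 in dHEP chow, too few for a share under 0.05: 3315 genes (highest other 0) in FF alcohol, 2754 (11) in dHEP alcohol and 3769 (0) in dHEP chow. Over all 35 splits, most of which mix an animal's tumor and non-tumor liver within a group, the real one was the 1 as large in FF alcohol (highest other 2) and in dHEP alcohol (39). Several splits were as large for FF diet in non-tumor liver (73 genes, 5 of 35 splits, highest other 510) and dHEP diet in tumors (1 gene, 6 of 35, highest other 263). Chance is not excluded for these either. The 510 came from FF-503, FF-595, FF-157 and FF-159 against FF-523, FF-581 and FF-158, which points to a structure of the samples other than diet. With a real count of 0 every split is as large: genotype on alcohol in tumors (35 of 35; highest other 1) and non-tumor liver (35 of 35; 5), FF diet in tumors (35 of 35; 0), and 100 drawn splits each for genotype by diet in tumors (7) and non-tumor liver (284) and for genotype by tissue (4). With 10 splits, too few for a share under 0.05, tissue gave 4153 (highest other 1) in FF chow and 3769 (4) in dHEP chow, and genotype on chow gave 0 in tumors (2; 10 of 10 as large) and in non-tumor liver (0; 10 of 10).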
